A study of Mus musculus with 6 samples.

How the data were processed

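RNA was measured by sequencing in 6 libraries of mouse Glu-tag cells, 3 labelled sh-control and 3 labelled sh-IRS2, which are called shControl and shIRS2 here with the replicate number of each title. Per the labels' protocols, RNA was taken up in TRIzol, required an integrity number above 7, and was enriched by poly(A) selection or ribosomal RNA depletion according to the organism. Libraries were made strand-specific by dUTP incorporation and read as paired ends of 150 bp, per the labels' protocols. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, its strand setting and its treatment of reads shared between genes are not given in the sources used here. Counts of overlapping genes, antisense pairs, pseudogenes and close paralogs are therefore uncertain.

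The authors deposited a table of raw read counts per gene, whole numbers with no normalization, for 54532 genes with Ensembl mouse identifiers. The authors deposited a second table of FPKM values for the same libraries. Within each library the FPKM values equal the count divided by the listed gene length and by a total that is the same for every gene. That total was 0.985 to 1.02 times the sum of the counts. The columns of both tables carry short names rather than the titles. The columns beginning NC were read as the sh-control samples and the columns beginning S as the sh-IRS2 samples, with the number of the title. This reading rests on the names alone and was not taken from the values. No column of per-sample values was left unused.

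Every row of the count table had a gene name. Of the 54532 genes, 54409 were also in GENCODE release M21, and 53499 of these had the same start and end, which is 98.3%. Coordinates are those of the count table, in mm10. Library totals ran from 14991019 to 19790073 counts, a ratio of 1.32. A total of 0 counts over all 6 libraries allows a level of up to 0.0295 CPM (counts per 1000000 counts of the library), taken as 3 counts over the sum of the 6 totals. Intervals and such limits cover counting error, and reads without molecular identifiers are not independent molecules.

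Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as its argument, which left 13472 genes holding 99.9% of all counts. Libraries were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood test with robust dispersions, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. All adjusted p-values for genes come from this edgeR fit unless another tool is named. All tests were two-sided. Standard errors and 95% intervals of log2 fold changes come from the same fit. Irs2 was also compared by an exact permutation test of log2 CPM, for which 3 libraries against 3 cannot give a p below 0.1.

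Before the data were examined, 44 gene lists were fixed, for insulin signalling, the cell cycle, adhesion and migration, matrix, enteroendocrine identity, metabolism, stress, technical signs and markers of other cell types. The 41 lists with at least 3 tested genes were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, and fry was run as a test that does not compare a list with other genes. P-values were adjusted over the lists. Members were counted over all genes tested and adjusted over the list alone. The adjustment over a list alone makes no allowance for the number of lists, so some such calls are expected by chance.

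The genes to be named were also set by a rule before the data were examined. Irs2 came first. Among genes past the threshold, with groups that do not overlap, a mean of at least 5 CPM and a protein-coding name that is not provisional, the 12 with the largest increase, the 12 with the largest decrease and the 5 with the highest level among those changed at least 2-fold were to be named. No gene met that part of the rule. In each list described, up to 4 members with the smallest edgeR p-values could be named, and 27 genes of insulin signalling, proliferation, adhesion, matrix and endocrine identity were to be named whatever their result. Genes outside the rule are said to have been chosen after their values were seen. Results for some genes and for a gene list are not reported here.

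The series text calls the libraries biological triplicates, while the description of every sample carries the same replicate number and only the titles number them 1 to 3. No label says that a number marks a shared culture or day, so p-values measure the spread between these samples, part of which may be technical. Whether the numbers pair the libraries was checked by correlating each library's deviations from its group mean. The correlation was 0.167 for the libraries numbered 1, 0.576 for those numbered 2 and 0.260 for those numbered 3. All 3 lay above the limit of 0.1 set beforehand, so the numbers were treated as pairs in the replicate block and in ratios given by number. The main fit has no term for them. Deviations cancel out within a group, so libraries numbered 2 that stand apart in both groups raise every correlation among the numbers 1 and 3. Passing the limit thus says little about the pairs numbered 1 and 3. The pairing thus comes from the values and the titles, not from a stated design. The shControl library numbered 1 correlated with the shIRS2 library numbered 3 at 0.189, and the shControl library numbered 3 with the shIRS2 library numbered 1 at 0.199, both above the value for the pair numbered 1. A fit with the replicate number as a block was planned as an alternative and is given beside a result where it changes a call or a count.

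Counts of library pairs differed by a chi-square per degree of freedom of 4.61 to 26.7, so no library was a copy of another. Alternatives planned beforehand were DESeq2 1.42.0 and its size factors, library size only, upper-quartile factors, no filter, a filter at 1 CPM in 3 libraries, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), FPKM of at least 1, a test against a 1.5-fold change, the replicate block, and leaving out each library in turn. The edgeR fit without the replicate block was tested on simulated counts with the real means and library sizes. Each library was drawn independently, with no difference between the replicate numbers, so recovery and false calls may differ in the real libraries. The fit with the block was not simulated. For shIRS2 against shControl, over 13472 simulated genes, edgeR recovered 33 of 84 genes changed 1.5-fold, 40 of 54 changed 2-fold and 61 of 62 changed 4-fold, with 2 false calls. All 6 libraries were used in every comparison unless a left-out library is named.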

Results

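Gene expression was measured in Glu-tag cells, a mouse enteroendocrine line known for producing proglucagon-derived peptides and used by the study as a model of small intestinal neuroendocrine tumours. The design compared cells carrying a control hairpin with cells carrying a stable hairpin against Irs2, the insulin receptor substrate that links insulin and IGF receptors to phosphoinositide 3-kinase. There were 3 libraries in each group. The question posed by the series is which transcripts respond when Irs2 is silenced, with proliferation, migration and invasion as the processes of interest. The control libraries numbered 1 to 3 held 14991019, 19790073 and 17711094 counts and the libraries labelled shIRS2 held 16985361, 16428788 and 15654814. Between 19943 and 20942 genes were detected per library.

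Irs2 RNA was not lower in the libraries labelled shIRS2. Its level was 29.5 ± 6.05 CPM (mean ± SD, n = 3) in the control libraries and 32.9 ± 5.22 CPM (n = 3) in the libraries labelled shIRS2. The control libraries held 31.6, 22.7 and 34.3 CPM and the libraries labelled shIRS2 held 31.4, 28.6 and 38.7 CPM, from 473, 450 and 608 against 533, 470 and 606 counts. The log2 fold change was 0.17 (SE 0.17, 95% interval -0.20 to 0.54), with an edgeR adjusted p of 1.00. The exact permutation test gave a two-sided p of 0.6, where 0.1 is the smallest that 3 libraries against 3 allow. The interval allows a fall of at most 12.8%. In the fit with the replicate block the log2 fold change was 0.18 (SE 0.09, 95% interval -0.01 to 0.37), with an edgeR adjusted p of 0.570, and the interval allows a fall of at most 0.879%. The pairs numbered 1, 2 and 3 had log2 ratios of 0.02, 0.34 and 0.18. Leaving out single libraries moved the log2 fold change between 0.02, without the control library numbered 2, and 0.29, without the control library numbered 3. Irs2 (ENSMUSG00000038894) lies on the minus strand of chromosome 8, from 10984681 to 11008458 in mm10. The annotated gene 9530052E02Rik, which overlaps it, held 7 counts in all 6 libraries. Because Irs2 goes against the label, the groups are named by their labels throughout, and each direction below is that of the libraries labelled shIRS2 against the control libraries.

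**Figure D1:**
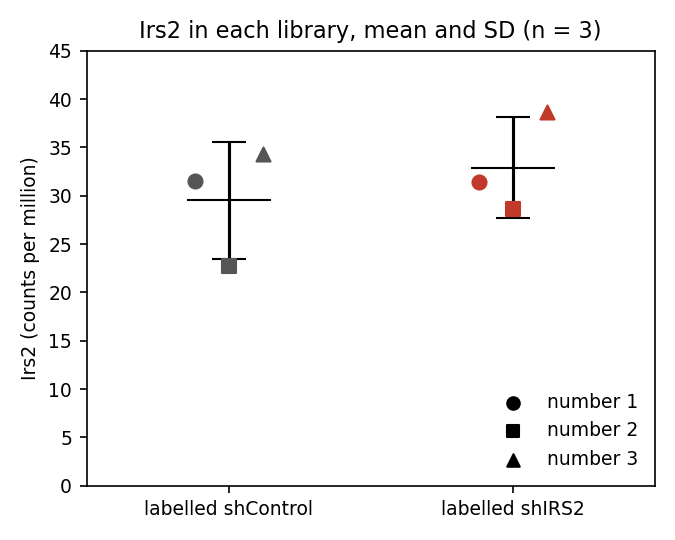
Irs2 in CPM for each of the 6 libraries, with the mean and SD of the 3 libraries of each group as horizontal and vertical bars and the replicate number as the symbol. The control libraries lie between 22.7 and 34.3 CPM and the libraries labelled shIRS2 between 28.6 and 38.7 CPM.

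No gene separated the libraries labelled shIRS2 from the control libraries at an adjusted p of 0.05. The edgeR test called 0 of 13472 genes, with 262 at an unadjusted p under 0.05 where 674 would be expected by chance. That fit has no term for the replicate number, so differences between the numbers stay in its error. With the replicate block 1234 genes lay under that p, as given below. DESeq2 called 0 genes, with 207 at an unadjusted p under 0.05, limma-voom called 0, with 266, and limma on log2(FPKM + 1) called 0, with 330. Every tested gene named below had an edgeR adjusted p of 1.00. In 439 genes all 3 libraries labelled shIRS2 lay above all 3 control libraries and in 416 they lay below, together 6.35% of the genes tested. Chance gives 10% for libraries that do not differ by replicate number, and these did, so the 2 shares are not directly comparable. Among the 9040 genes with a mean of at least 10 CPM, 1 had an absolute log2 fold change of at least 1 and 21 of at least 0.5. The 95% interval excluded a 2-fold change either way in 8984 of these genes, which is 99.4%, and its median half-width was 0.26 on the log2 scale.

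A few genes passed the threshold in other fits, and apart from Vcan, which the rule for gene lists names, those named here were chosen after their values were seen. With the replicate block, edgeR had 1234 genes at an unadjusted p under 0.05, against the same 674 expected by chance. Other divisions of the libraries into 3 and 3 that part all numbered pairs had 1117, 137 and 438 such genes in that fit. A grouping that mixes the labels can thus give a similar excess. For the real groups the blocked fit called 1 gene. This was the processed pseudogene Gm44126, at 1.38 ± 0.721 CPM in the control libraries and 5.55 ± 2.84 CPM in the libraries labelled shIRS2 (n = 3 each). Its blocked log2 fold change was 2.03 (SE 0.25) and its adjusted p 0.0114, and it was higher in all 3 numbered pairs, by 1.91, 2.50 and 1.30. Reads of a processed pseudogene can come from its parent gene. DESeq2 with the replicate block called 4 genes, among them Gm44126, Ptms and Taldo1. Ptms, which encodes the small acidic nuclear protein parathymosin, had a log2 fold change of 0.42 and an adjusted p of 0.0201. Taldo1, which encodes transaldolase of the pentose phosphate pathway, had a log2 fold change of 0.43 and a DESeq2 adjusted p of 0.0367. Without a filter on low counts edgeR called 6 genes, which were Gm44126, Gm2446, Pygm, Snx14, Gm47283 and Vcan, with adjusted p-values from 5.65e-09 to 0.0299. Among them were Pygm, the glycogen phosphorylase of muscle, at a log2 fold change of -2.06, Snx14, a sorting nexin gene, at -0.60, and Vcan, which encodes the proteoglycan versican, at 0.47. In the filtered fit with the replicate block, only Gm44126 of these 6 genes passed, and the blocked adjusted p was 0.125 for Pygm, 0.558 for Snx14 and 0.658 for Vcan. In the pair numbered 3 the log2 ratio was of the other sign for Snx14, at 0.04, and for Vcan, at -0.07, where the pairs numbered 1 and 2 had 0.85 and 0.61 for Vcan. For Gm47283 it was of the other sign in the pair numbered 1, at 0.19.

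The study's question centres on insulin signalling and growth, and genes of these groups lay close to equal in both sets of libraries. Of 41 tested components of the insulin, phosphoinositide 3-kinase and mTOR pathway, 18 had a positive and 23 a negative log2 fold change, with a median of -0.02 and a camera adjusted p of 0.884. Irs1, the other widely used receptor substrate, had 41.2 ± 3.73 CPM in the control libraries and 43.8 ± 0.956 CPM in the libraries labelled shIRS2 (n = 3 each), and Irs4 had 0 counts in all 6 libraries. The insulin receptor gene Insr stood at 55.1 ± 0.790 against 52.1 ± 3.55 CPM, the IGF receptor gene Igf1r at 52.8 ± 1.92 against 55.6 ± 3.59 CPM, and Foxo1, a transcription factor restrained by Akt, at 4.95 ± 0.856 against 4.83 ± 0.894 CPM. Pik3r1, the main regulatory subunit of phosphoinositide 3-kinase, had a log2 fold change of 0.22 (SE 0.10), and Mtor, the kinase of the growth-control complexes, one of -0.14 (SE 0.09). The 22 tested FoxO target genes had a median of 0.03 and a camera adjusted p of 0.583, and 0.0409 without the library labelled shIRS2 numbered 2. Leaving out that library makes the numbers unequal between the groups. FoxO target genes were lower in the libraries numbered 2, at a median log2 contrast of -0.31, so that pass can come from the numbers. Cited2, a transcriptional co-regulator in that list, had a log2 fold change of 0.36 (SE 0.14), and with the replicate block it was 1 of 5 members of the list that were higher adjusted over the list alone, against 0 without it.

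Most cell-cycle genes were expressed in all 6 libraries, and they did not pass the test. All 45 replication genes, all 45 mitotic genes and 17 of 22 cyclins and inhibitors had a mean above 1 CPM. Of these 22 genes 3 had 0 counts in all libraries. The 45 genes of DNA replication and the G1/S step had a median log2 fold change of -0.01 and a camera adjusted p of 0.741, and the 45 mitotic genes had 0.01 and 0.600. Mki67, a marker of cycling cells, stood at 618 ± 14.4 CPM in the control libraries and 645 ± 51.1 CPM in the libraries labelled shIRS2 (n = 3 each). Pcna, the sliding clamp of the replication fork, stood at 438 ± 31.95 against 433 ± 28.9 CPM and Ccnd1, which encodes cyclin D1, at 271 ± 79.0 against 262 ± 78.6 CPM. The cyclin-dependent kinase inhibitor genes Cdkn1a and Cdkn1b had log2 fold changes of 0.30 (SE 0.43) and 0.23 (SE 0.23). Among replication genes the smallest p-values belonged to the replication-complex genes Gins1 at -0.31 (SE 0.14) and Rfc4 at -0.20 (SE 0.10). The 17 tested cyclins and inhibitors had a camera adjusted p of 0.784. Adjusted over the list alone, 0 members of these 3 lists passed in the edgeR fit, as over all genes. With the replicate block 2 of the 17 cyclins and inhibitors were higher adjusted over the list alone. Cdkn1a was among them, at a log2 fold change of 0.30 (SE 0.07) and an adjusted p of 0.0177, and higher in all 3 numbered pairs.

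Genes for the folding of proteins in the endoplasmic reticulum were slightly higher in the libraries labelled shIRS2. Of 22 tested genes of the unfolded protein response, 21 had a positive log2 fold change, with a median of 0.13, and the list passed camera at an adjusted p of 0.000604. The call was lost at an adjusted p = 0.896 with an estimated correlation, which was the smallest value that version gave for any list. Calr, a calcium-binding chaperone, stood at 948 ± 72.5 CPM in the control libraries and 1104 ± 5.40 CPM in the libraries labelled shIRS2 (n = 3 each), and Pdia4, a protein disulfide isomerase, at 314 ± 39.0 against 368 ± 20.8 CPM. The chaperone genes Hspa5 and Hsp90b1 had log2 fold changes of 0.19 (SE 0.10) each. The list median was 0.20 and 0.16 in the pairs numbered 1 and 2 and -0.01 in the pair numbered 3. Without the control library numbered 2 the adjusted p of camera was 0.149. No member passed over all genes or adjusted over the list alone, and with the replicate block 4 members were higher adjusted over the list alone, Calr and Pdia4 among them.

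Genes for matrix proteolysis and markers of fibroblasts were also slightly higher in the libraries labelled shIRS2. Of 28 tested genes of matrix proteolysis, 23 had a positive log2 fold change, with a median of 0.14 and a camera adjusted p of 0.000867. Of 11 tested fibroblast markers, 9 were positive, with a median of 0.18 and a camera adjusted p of 0.0151. Both calls were lost at an adjusted p = 0.896 with an estimated correlation. In the pairs numbered 1, 2 and 3 the median was 0.27, 0.21 and -0.03 for matrix proteolysis and 0.25, 0.22 and 0.11 for the fibroblast markers. Mmp14, a membrane-anchored metalloproteinase, stood at 145 ± 13.5 CPM in the control libraries and 172 ± 8.98 CPM in the libraries labelled shIRS2 (n = 3 each), a log2 fold change of 0.26 (SE 0.10). The gelatinase genes Mmp2 and Mmp9 had log2 fold changes of 0.58 (SE 0.21) and 0.46 (SE 0.38), at means of 3.23 and 2.97 CPM in the control libraries. Mmp3, which encodes stromelysin, had 0.49 (SE 0.19), with a log2 ratio of -0.17 in the pair numbered 3. Igfbp5, which encodes an IGF-binding protein and belongs to the fibroblast markers, rose when adjusted over the list alone, from 1.28 ± 0.412 to 2.92 ± 0.491 CPM, with a log2 fold change of 1.20 (SE 0.30) and an adjusted p of 0.0250, and it was higher in all 3 numbered pairs. Adjusted over the list alone, 5 fibroblast markers, Igfbp5 and Col3a1 among them, and 2 genes of matrix proteolysis, Mmp14 among them, were higher with the replicate block. Col3a1, a fibrillar collagen, stood at 646 ± 187 against 824 ± 64.7 CPM. Without the control library numbered 2 the camera adjusted p was 0.0961 for both lists, and for the fibroblast markers it was 0.0885 without the control library numbered 1 and 0.105 without the library labelled shIRS2 numbered 3.

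Transcripts of the mitochondrial genome were the remaining group that passed camera. Of 14 tested genes, 13 had a positive log2 fold change, with a median of 0.18 and a camera adjusted p of 0.000818, which was lost at an adjusted p = 0.896 with an estimated correlation. The cytochrome oxidase gene mt-Co1 stood at 5088 ± 422 CPM in the control libraries and 5687 ± 343 CPM in the libraries labelled shIRS2 (n = 3 each), and mt-Rnr2, the large mitochondrial ribosomal RNA, at 176 ± 18.7 against 198 ± 7.65 CPM. Adjusted over the list alone, 6 members, mt-Rnr2 among them, were higher with the replicate block, against 0 without it. The list median was 0.40 in the pair numbered 1 and 0.07 and 0.09 in the other pairs. The camera adjusted p was 0.165 without the control library numbered 1, 0.0763 without the control library numbered 3 and 0.135 without the library labelled shIRS2 numbered 2. Mitochondrial transcripts, a common sign of RNA or cell state, took 1.25%, 1.63% and 1.40% of the counts in the control libraries and 1.61%, 1.71% and 1.44% in the libraries labelled shIRS2.

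Over all lists, camera called 4 of 41, all higher in the libraries labelled shIRS2, and 0 with an estimated correlation. With an estimated correlation no list had an adjusted p under 0.896. Between the replicate numbers that version also called 0 lists, though 31 of 34 ribosome biogenesis genes differed there. A call lost in that version therefore says little about a single list. The other 37 lists had camera adjusted p-values from 0.0657 to 0.995. Fry called 0 lists in a common direction, at an adjusted p of 0.987 for each of these 4 lists. When changes in either direction counted, fry called 2 lists, the replication-dependent histones at an adjusted p of 0.0413 and the neuronal and glial markers at 0.0423, and with the block 3, adding the cyclins and kinase inhibitors at 0.0448. The number of lists called was 7 without the control library numbered 3 and 9 without the library labelled shIRS2 numbered 1 or numbered 2. With both libraries numbered 2 left out, an alternative chosen after seeing the data, 7 lists were called.

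With the replicate block 7 lists passed camera, the 4 above and 3 more. Cholesterol synthesis was lower in the libraries labelled shIRS2, with 6 of 25 genes positive, a median log2 fold change of -0.08 and a blocked adjusted p of 0.000397, against 0.0657 without the block. Its medians in the pairs numbered 1, 2 and 3 were -0.10, -0.08 and -0.21. Ribosome biogenesis was lower, with 2 of 34 genes positive, a median of -0.08 and the same blocked adjusted p of 0.000397, against 0.0927, and pair medians of -0.04, -0.09 and -0.06. Hypoxia-response genes were higher, with 17 of 20 positive, a median of 0.14 and 0.00468, against 0.142, and pair medians of 0.25, 0.13 and -0.05 in the pairs numbered 1, 2 and 3. All 7 calls were lost at a blocked adjusted p = 0.804 with an estimated correlation. Over all lists, members past the threshold adjusted over the list alone numbered 3 without the block and 54 with it, a gene being counted in each list that holds it. Lists not described elsewhere held 2 of these for nutrient sensing, 2 for immediate early and feedback genes of MAP kinase signalling, and 1 each for Wnt targets, glycolysis and p53 targets, all higher, and the hypoxia list held 1, also higher. The calls for glycolysis and hypoxia and 1 of the 2 for nutrient sensing were the same gene, Slc2a1. The p53 call was Cdkn1a, already named among the cyclins and inhibitors. Calls adjusted over the list alone are not adjusted over the lists, so some are expected by chance. A division of the libraries that mixes the labels had 1117 genes at an unadjusted p under 0.05 in the blocked edgeR fit, against 1234. No count of members adjusted over the list alone is given for that division. In cholesterol synthesis 4 genes were lower with the block adjusted over the list alone. Among these were the lanosterol synthase gene Lss, at 58.1 ± 12.5 CPM in the control libraries and 45.7 ± 6.78 CPM in the libraries labelled shIRS2 (n = 3 each), the isoprenoid isomerase gene Idi1 and the sterol demethylation gene Msmo1. The blocked log2 fold changes of Lss, Idi1 and Msmo1 were -0.32, -0.32 and -0.26. Gar1, a component of the particles that modify ribosomal RNA, had a log2 fold change of -0.27 (SE 0.19) and Adm, which encodes the hypoxia-induced peptide adrenomedullin, 0.24 (SE 0.23). The fatty acid synthesis list did not pass in either fit, at 0.0927 and 0.0609 with the block, and its members Me1, a source of NADPH, and Acacb, an acetyl-CoA carboxylase, had log2 fold changes of -0.24 (SE 0.08) and -0.50 (SE 0.18). Of its genes 3 were lower with the block adjusted over the list alone, against 0 without it, among them Me1 at an adjusted p of 0.0376 and Acacb at 0.0459, both lower in all 3 numbered pairs. Without the block, leaving out the control library numbered 3 gave camera adjusted p-values of 0.00331 for cholesterol synthesis, 0.00331 for ribosome biogenesis and 0.0246 for hypoxia, and leaving out the library labelled shIRS2 numbered 2 gave 0.0326, 4.13e-07 and 0.000249. Cholesterol synthesis also passed without the library labelled shIRS2 numbered 1, at 0.00206, and ribosome biogenesis without the control library numbered 1, at 0.00465. Fatty acid synthesis passed without the control library numbered 2 or the library labelled shIRS2 numbered 1, at 0.0267 and 0.0213. Leaving out 1 library makes the numbers unequal between the groups. In the libraries numbered 2, ribosome biogenesis was higher and hypoxia lower, at median log2 contrasts of 0.52 and -0.62. The passes of these lists with 1 library left out can thus come from the numbers.

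**Figure D2:**
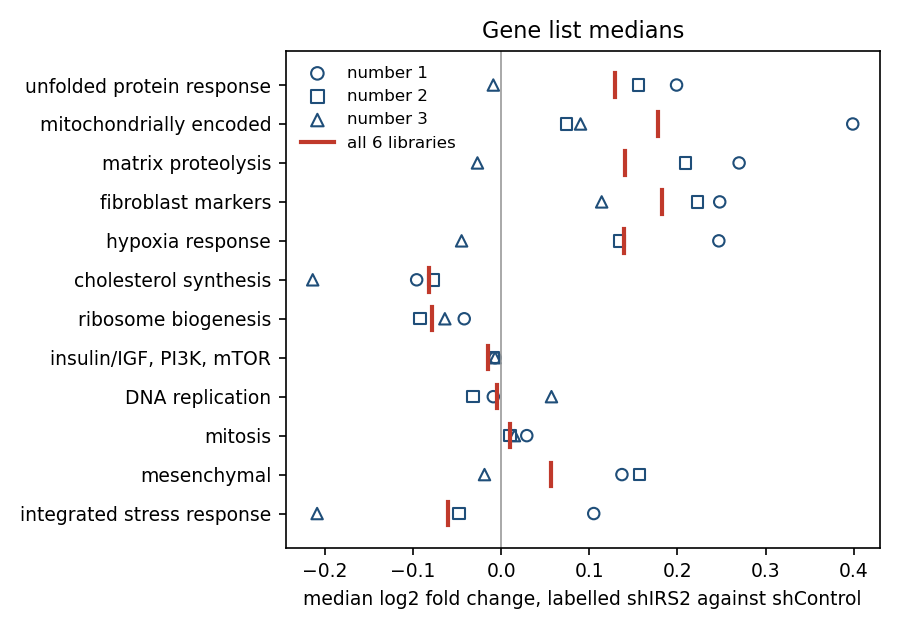
Median log2 fold change of 12 gene lists, libraries labelled shIRS2 against control libraries, over all 6 libraries as red bars and within each numbered pair as open symbols. The medians over all libraries lie between -0.08 and 0.18, and the unfolded protein response has 0.20, 0.16 and -0.01 in the pairs numbered 1, 2 and 3.

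Genes tied to migration and invasion did not pass the test apart from the proteolysis list. The 35 tested mesenchymal genes had a median log2 fold change of 0.06 with 26 positive, and a camera adjusted p of 0.0927. The list passed at 0.0252 without the control library numbered 3 and at 0.0366 without the library labelled shIRS2 numbered 1. Vim, the intermediate filament of mesenchymal cells, stood at 1852 ± 31.95 CPM in the control libraries and 2033 ± 56.4 CPM in the libraries labelled shIRS2 (n = 3 each), and Fn1, which encodes fibronectin, at 275 ± 76.3 against 337 ± 15.7 CPM. The transcription factor genes Snai1, Snai2 and Zeb1, which repress epithelial genes, had log2 fold changes of 0.04 (SE 0.14), -0.11 (SE 0.17) and -0.03 (SE 0.10). The mesenchymal regulator Prrx1 had 0.29 (SE 0.11). The camera adjusted p was 0.908 for 18 tested epithelial junction genes, 0.741 for 35 integrin and focal adhesion genes and 0.600 for 33 collagens and matrix genes. In the matrix list Col17a1, a collagen of hemidesmosomes, fell when adjusted over the list alone, from 0.939 ± 0.140 to 0.244 ± 0.0568 CPM, with an adjusted p of 0.0300 and a log2 fold change of -1.93 (SE 0.41), on 61 counts in all, and was lower in all 3 numbered pairs. Vcan stood at 165 ± 26.7 against 226 ± 35.7 CPM, and the laminin gene Lama3 at 39.4 ± 8.80 against 29.1 ± 2.86 CPM. With the block, 8 members of the matrix list, Col3a1 among them, were higher and 3, Col17a1 and Lama3 among them, were lower adjusted over the list alone. In the neuronal and glial list Elavl3, a neuronal RNA-binding protein gene, fell when adjusted over the list alone, from 1.61 ± 0.257 to 0.691 ± 0.117 CPM, with a log2 fold change of -1.21 (SE 0.31) and an adjusted p of 0.0189. That list had a camera adjusted p of 0.741, and 0.0454 without the library labelled shIRS2 numbered 1. With the block, 1 of its members was higher and 1, Elavl3, lower adjusted over the list alone.

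Most hormone genes and most enteroendocrine transcription factor genes were at or near 0 in both groups, while part of the secretory granule genes were expressed. Proglucagon (Gcg), peptide YY (Pyy), chromogranin A (Chga) and somatostatin receptor 2 (Sstr2) had 0 counts in all 6 libraries, which allows up to 0.0295 CPM. Cck, which encodes cholecystokinin, had 10 counts in all, and Syp, the synaptic vesicle protein synaptophysin, stood at 0.706 ± 0.0281 CPM in the control libraries and 0.798 ± 0.254 CPM in the libraries labelled shIRS2 (n = 3 each). Of 22 hormone genes, 16 had 0 counts in all libraries and 1 had a mean above 1 CPM, Tph1, the enzyme that starts serotonin synthesis, at 3.36 ± 0.963 against 4.89 ± 1.89 CPM. Of 40 enteroendocrine transcription factor genes, 23 had 0 counts and 5 lay above 1 CPM, among them Etv1 at 93.7 ± 18.2 against 112 ± 21.97 CPM and Pax6 at 24.9 ± 2.99 against 22.6 ± 2.50 CPM. With the block, Tph1 and Etv1 were higher adjusted over the list alone, against 0 members of either list without it. Tph1 had a blocked log2 fold change of 0.53 (SE 0.19) and an adjusted p of 0.0279 over the 2 hormone genes tested, and Etv1 0.26 (SE 0.08) and 0.0323, and both were higher in all 3 numbered pairs. Of 45 secretory granule genes, 19 lay above 1 CPM, led in p-value by Stx1a, a syntaxin of exocytosis, at 9.55 ± 1.15 against 7.68 ± 1.55 CPM, and the list had a camera adjusted p of 0.360. The 6 tested factor genes had a camera adjusted p of 0.921.

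Epithelial genes were also low and mesenchymal genes high in both groups. Cdh1, which encodes E-cadherin, had 14 counts in all, Epcam 1 count and Cdh2, which encodes N-cadherin, 0 counts. Krt8, a keratin of simple epithelia chosen after its values were seen, stood at 396 ± 14.4 CPM in the control libraries and 396 ± 19.7 CPM in the libraries labelled shIRS2 (n = 3 each). Of 42 epithelial junction genes 13 lay above 1 CPM, which is 31.0%, against 35 of 43 mesenchymal genes, which is 81.4%. Spp1, which encodes osteopontin, stood at 1295 ± 116 against 1499 ± 138 CPM. Twist1, a mesenchymal transcription factor gene chosen after its values were seen, stood at 73.3 ± 13.1 against 73.0 ± 7.32 CPM. Markers of other cell types lay above 1 CPM in 9 of 14 genes for intestinal stem cells, 11 of 21 for fibroblasts, 5 of 16 for endothelium, 6 of 22 for neurons and glia and 5 of 22 for immune cells. They did so in 3 of 18 genes for enterocytes, 2 of 14 for tuft cells, 1 of 16 for goblet and Paneth cells and 0 of 17 for pancreatic islets.

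**Figure D3:**
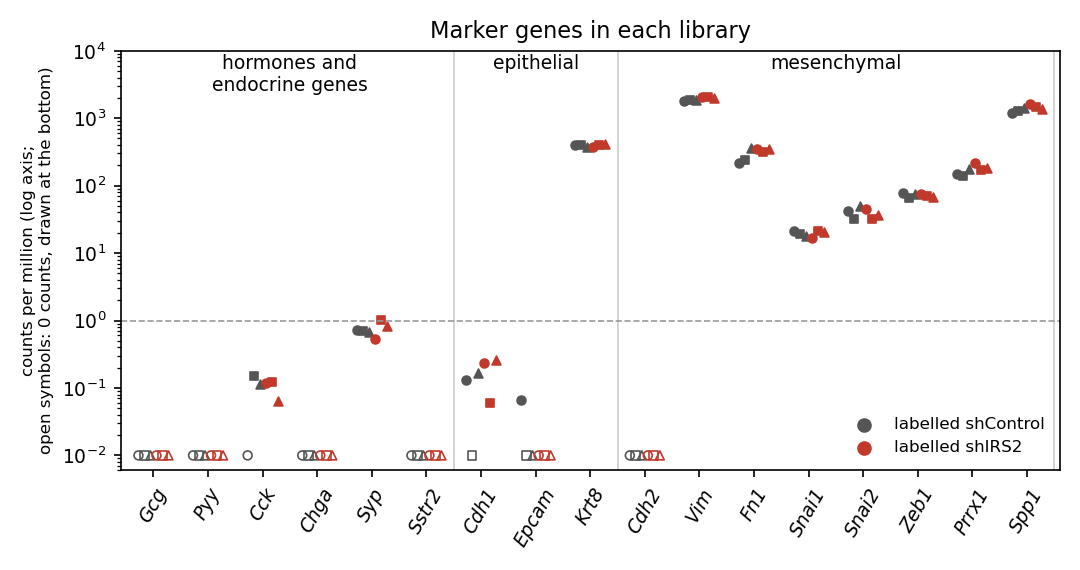
CPM on a log axis of 17 marker genes in each of the 6 libraries, with the group as the colour, the replicate number as the symbol and open symbols at the bottom for 0 counts. Gcg, Pyy, Chga, Sstr2 and Cdh2 have 0 counts in every library, while Vim lies between 1822 and 2080 CPM.

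The libraries were similar to each other and differed more by replicate number than by group. Pearson correlations of log2 CPM across genes, which are not independent replicates, lay between 0.985 and 0.993. The first principal component, with 41.9% of the variance, placed the libraries numbered 2 at 28.7 and 23.5 and the other 4 between -16.9 and -6.84. The second component, with 19.9%, placed the control library numbered 1 at -25.1 and the other 5 between -7.60 and 14.0. Without that library, and without some others named above, the camera calls for mitochondrial transcripts and fibroblast markers were lost. The biological coefficient of variation was 13.2% without and 7.05% with the replicate block. The FPKM table gave log2 fold changes that correlated with those of the counts at a Pearson coefficient of 0.864 across 13472 genes. A fit with group and replicate number, chosen after seeing the data, found 2638 genes that differed between the numbers at an edgeR adjusted p of 0.05. Trib3, a pseudokinase gene induced by amino acid shortage, stood at 22.4 and 21.6 CPM in the libraries numbered 2 and between 101.5 and 134 CPM in the other 4, and Tsr1, a factor of ribosome assembly, at 174 and 157 against 96.1 to 98.7 CPM.

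**Figure D4:**
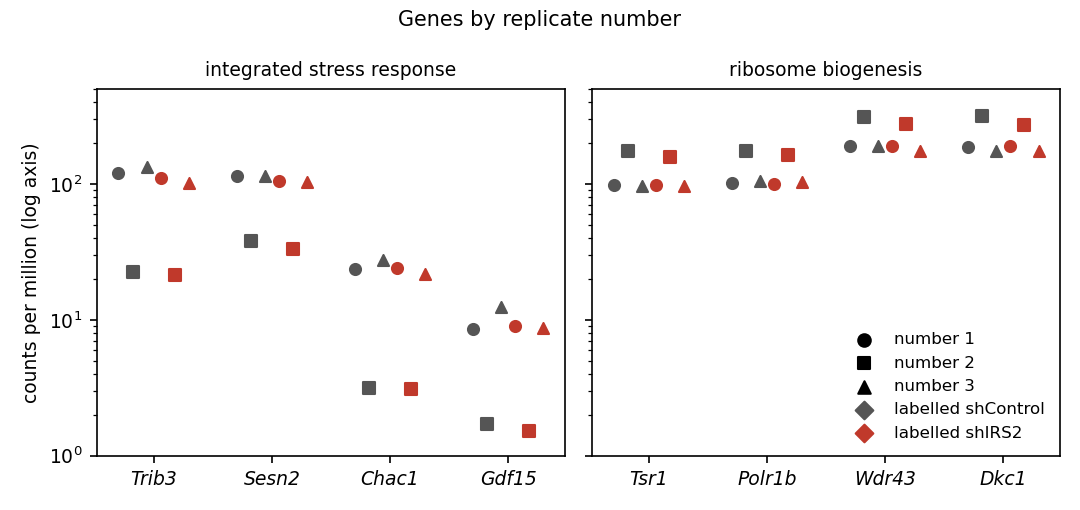
CPM on a log axis of 4 genes of the integrated stress response and 4 genes of ribosome biogenesis in each library, with the replicate number as the symbol and the group as the colour, the genes chosen after their values were seen. Trib3 lies at 22.4 and 21.6 CPM in the libraries numbered 2 and at 101.5 CPM or more in the other 4, and Tsr1 at 174 and 157 CPM against 98.7 CPM or less.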

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

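The alternatives that leave out both libraries numbered 2 and that add the replicate block to DESeq2 were chosen after seeing the data, and all others were planned. Irs2 kept a positive log2 fold change in all 20 alternatives, between 0.02 and 0.29, with a smallest adjusted p of 0.570, under the replicate block. The count of genes past the threshold was 0 in the edgeR fit (262 at an unadjusted p under 0.05) and stayed 0 with DESeq2 (207), limma-voom (266), limma on FPKM (330), the other scalings, the stricter filter, the test against a 1.5-fold change, each library left out and both libraries numbered 2 left out (342). It was 6 without a filter on low counts, 4 of them with an absolute log2 fold change of at least 1, where 25979 genes entered the fit. It was 1 with the replicate block (1234 at an unadjusted p under 0.05), with 1 of that size, and 4 in DESeq2 with the replicate block, with 1 of that size. The block takes the difference between numbers out of the error. For the filter and for the lists below, the cause was not tested. Of 1763 values for 89 named genes under alternatives, 2 passed the threshold, among them that for Vcan without a filter, and 28 others had the other sign. The 89 leave out Gm44126, Gm2446, Pygm, Snx14, Gm47283, Ptms and Taldo1. These were chosen after their values were seen and passed in the fits given above. The replicate block also moved the members past the threshold adjusted over the list alone, counted in each list that holds them, from 3 to 54. It moved the lists called by fry in either direction from 2 to 3, adding cyclins and inhibitors at 0.0448. Apart from these, the counts above and the 3 lists named with it below, it changed no other call. Among the scalings, library size only moved the median of all genes most, by -0.0125 on the log2 scale. At this depth the median 95% half-width was 0.32 on the log2 scale over all genes tested.

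Camera called 4 lists, and 10 with limma-voom, 9 with log2(FPKM + 1), 9 with FPKM of at least 1, 7 with the replicate block, 7 with both libraries numbered 2 left out, 3 to 9 with a library left out, 0 with an estimated correlation and 0 with fry. With an estimated correlation the unfolded protein response, matrix proteolysis, mitochondrial transcripts and fibroblast markers each had an adjusted p of 0.896, and with fry 0.987. Under limma-voom further lists passed, namely mesenchymal genes at 0.0210, cholesterol synthesis at 0.0161, fatty acid synthesis at 0.0336, hypoxia at 0.0431, ribosomal proteins at 0.0241 and ribosome biogenesis at 0.0161. With log2(FPKM + 1) mesenchymal genes passed at 0.0462, cholesterol synthesis at 0.0277, fatty acid synthesis at 0.0479, ribosomal proteins at 0.0462 and ribosome biogenesis at 0.0469. With FPKM of at least 1 mesenchymal genes passed at 0.0157, collagens and matrix at 0.0132, cholesterol synthesis at 0.0132, ribosomal proteins at 0.0394 and ribosome biogenesis at 0.0397. With the replicate block cholesterol synthesis passed at 0.000397, ribosome biogenesis at 0.000397 and hypoxia at 0.00468. With both libraries numbered 2 left out fatty acid synthesis passed at 0.0443, hypoxia at 0.0243 and ribosome biogenesis at 0.0243.

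With each library left out in turn, the camera adjusted p ran from 7.40e-07 to 0.149 for the unfolded protein response, 4.40e-09 to 0.165 for mitochondrial transcripts, 0.00331 to 0.0961 for matrix proteolysis and 0.00331 to 0.105 for fibroblast markers. It ran from 0.0409 to 0.844 for FoxO targets, 0.0252 to 0.808 for mesenchymal genes, 0.00206 to 0.873 for cholesterol synthesis, 0.0213 to 0.706 for fatty acid synthesis, 0.000249 to 0.844 for hypoxia, 0.0137 to 0.885 for autophagy, 4.13e-07 to 0.974 for ribosome biogenesis and 0.0454 to 0.982 for neuronal and glial markers. For the integrated stress response it ran from 0.000126, lower in the libraries labelled shIRS2 without the control library numbered 2, to 0.972, and without the library labelled shIRS2 numbered 2 the list was reversed and higher at 0.0409. Leaving out any 1 library leaves the numbers unequal between the groups. Of 816 list values under alternatives, 696 did not pass in either fit, and 74 of these had the other sign.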

Other observations

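All comparisons between replicate numbers were chosen after the results were seen. So were the tests below of explanations for the Irs2 and enteroendocrine values, of GC content and length and of a shared day. The counts of lists over the splits that part all pairs, and of genes at an unadjusted p over splits, were also chosen then. The thinning to equal depth and the other counts over splits were written before their results. The fit behind the Irs2 interval and the enteroendocrine lists were planned beforehand.

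Genes of the integrated stress response and of ribosome biogenesis differed between the replicate numbers in opposite directions. Of 34 tested stress-response genes, 27 differed between the numbers by edgeR's F test with group and number in the fit, and the median log2 contrast of the libraries numbered 2 against the other 4 was -0.56, with camera at an adjusted p of 2.65e-12. That call was lost at an adjusted p = 0.817 with an estimated correlation. Chac1, which degrades glutathione, stood at 3.13 and 3.10 CPM in the libraries numbered 2 and between 21.9 and 27.7 CPM in the other 4. Asns, which makes asparagine, stood at 254 and 234 CPM against 348 to 424 CPM, and Gdf15, a secreted stress cytokine, at 1.72 and 1.52 CPM against 8.61 to 12.5 CPM. Of 34 ribosome biogenesis genes, 31 differed, with a median contrast of 0.52 and a camera adjusted p of 5.26e-16, lost at an adjusted p = 0.707 with an estimated correlation. Polr1b, a subunit of RNA polymerase I, stood at 175 and 163 CPM in the libraries numbered 2 and between 101 and 105 CPM in the other 4.

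Further groups followed the numbers. In the hypoxia list 16 of 20 genes differed between the numbers, with a median contrast of -0.62, and in the autophagy and lysosome list 19 of 38, with -0.24. The camera adjusted p was 2.32e-07 and 1.01e-06. Camera called 7 lists between the numbers, the other 3 being FoxO targets, with a median contrast of -0.31 at an adjusted p of 0.00186, mitochondrial transcripts, with 0.33 at 0.00178, and the unfolded protein response, with -0.10 at 0.0423. The last 2 were also called between the groups. Apart from ribosome biogenesis, whose value is given above, these calls were lost at an adjusted p = 0.817 with an estimated correlation. Cdkn1a stood at 20.7 and 25.1 CPM in the libraries numbered 2 and between 44.4 and 68.7 CPM in the other 4, and Ccnd1 at 362 and 353 CPM against 208 to 234 CPM. Csf1, the macrophage growth factor gene, stood at 670 and 692 CPM against 331 to 411 CPM. Irs2 was also lower in the libraries numbered 2, at a log2 contrast of -0.377 and an edgeR adjusted p of 0.0107. Its contrast was -0.499 within the control libraries and -0.255 within the libraries labelled shIRS2. Among pairs of numbers, 2 against 1 differed in 2056 genes, 2 against 3 in 2884 and 3 against 1 in 32. Within the mitotic list 4 of 45 genes differed, and Mki67 stood between 603 and 702 CPM in all 6 libraries.

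Irs2 RNA was not lower in the libraries labelled shIRS2. Too few reads are argued against, since the lower end of the 95% interval was -0.20, where a 2-fold fall is -1, and labels exchanged between the groups are argued against for such a fall, since the lowest log2 ratio over every division into 3 and 3 was -0.35, more than 2 SD (0.26 each) above -1. Libraries labelled wrongly without an exchange are argued against in the same way if the numbers are right, since the lowest ratio over every division into 1 and 5 or 2 and 4 was -0.41, with the number in the fit unless both libraries of each number fell together. A hairpin that acted on the protein alone or was lost in culture, and 6 libraries of a single kind, cannot be told apart at a log2 fold change of 0.17, since no protein or hairpin values were analysed here. Biological silencing of Irs2 in these libraries thus remains untested at the level of the protein.

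Most hormone genes and most enteroendocrine factor genes lay at or near 0 counts in all 6 libraries. A loss of secretory genes as a class in counting is argued against, since 18 of 45 secretory granule genes lay above 1 CPM by more than 2 SD, while a loss of single genes was not tested. Dilution of hormone-producing cells stays open, because no table holds the level of such cells alone. The 22 hormone genes summed to at most 7.60 CPM in a library, of which Tph1 held 6.30 CPM, and Gcg had 0 counts. A candidate explanation, as a hypothesis, is cultured cells without most of an enteroendocrine program, as another line under this label or after its loss. It rests on 81.4% of mesenchymal genes against 31.0% of epithelial junction genes above 1 CPM, though dilution by other cells would give the same shares. The absence was not complete, since 5 of 40 enteroendocrine factor genes and 19 of 45 secretory granule genes lay above 1 CPM.

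The libraries numbered 2 differed from the other 4 in both groups. Library size is argued against, since after thinning to the smallest library the median contrast of the stress-response list was -0.56 and 28 of its genes were past the threshold, as many as before thinning. GC content and gene length are argued against, since the list median relative to all genes was -0.51 before and -0.47 after a loess correction, with 28 and 25 genes past the threshold. A shared culture or library day may lie behind the 2638 genes that differed between the numbers, and it cannot be told apart from other causes because no label gives a day. No biological explanation was tested, since the design names none for the numbers.

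The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. In the edgeR fit the real split called 0 genes and the highest other split 1. With 0 genes in the real split all 10 of 10 splits give as many by construction, so that count says nothing. The real split called 4 lists and the highest other 9, and 7 of 10 splits gave as many lists, but apart from the real one these 7 do not part all 3 numbered pairs and so set libraries of unequal numbers against each other. Among the 4 splits that part all 3 pairs, the real one called 4 lists and the highest other 3, so that 1 of 4 gave as many. In the fit with the block the real one called 7 lists and the highest other 12, and 2 of 4 gave as many. For genes in that fit the real one called 1 and the highest other 6, and 2 of 4 gave as many. At an unadjusted p under 0.05 the blocked edgeR fit had 1234 genes in the real split and 1117, 137 and 438 in the others. These 4 splits are likewise too few for a share under 0.05. The split of the control libraries numbered 1 and 2 and the library labelled shIRS2 numbered 2 against the rest, which keeps both libraries numbered 2 together, had 2851 genes at an unadjusted p under 0.05, against 262 for the real split.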
